A study of Phtheirospermum japonicum with 32 samples.

How the data were processed

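Roots of *P. japonicum* were profiled on 32 one-colour Agilent arrays, 24 from DMBQ-treated and 8 from mock-treated roots, and grouped by the treatment and time in the labels. Per the file headers and the submitters' processing notes, the authors scanned Cy3-labelled arrays and extracted spots with Agilent Feature Extraction 10.7.3. The deposited intensity of each spot is a background-subtracted, detrended linear signal that was not scaled between arrays. Per the file headers the deposited files also hold other values used here, flags per spot for signal well above background, non-uniformity, population outliers and saturation; no spot was saturated. The authors' table of normalized values was not used: its 32 value columns carry names that match no label, so no column could be assigned to a sample. Per the file headers there were 2 array designs, the first for replicates 1 and 2 and the second for replicate 3 and mock, each with 61657 non-control spots; 48023 probes, with identical contig names, occur on both.

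The intensity was averaged over spots of a probe on the log2 scale after leaving out non-uniform and outlier spots, and each array's 75th percentile was subtracted. The plan written before the data were examined took this percentile over non-control probes and used only probes present on all arrays. Because the designs differ in their other probes, the percentile was taken over the 48023 shared probes; the percentile over all probes of a design, the other reading of that plan, is given as an alternative since it lowers the counts. A probe was tested if it was well above background on all 3 arrays of at least 1 DMBQ time or on at least 3 mock arrays, which left 30968 probes for 30921 contigs. Tests were made with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with the data.table package (1.17.8), and figures with Python 3.11.15. A probe was called at a Benjamini-Hochberg adjusted p under 0.05 and at least a 2-fold difference. Each DMBQ time was compared with DMBQ 0 h in a fit of the 24 DMBQ arrays, with an F-test over the 7 times. DMBQ and mock were compared by the difference of their changes from 0 h in a fit of all 32 arrays.

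Where a group had no array well above background, only a bound is given: the bright group's mean against, on each dim array, the higher of the probe's own signal and the lowest signal among probes well above background. These bounds hold for the deposited background-subtracted signal, and normexp with its offset of 50 can give folds below them. They are computed from group means and carry no error, so a fold given as at least some value has no confidence level attached. Contigs were named by a rule fixed before the data were examined: since the files hold no annotation, at most 2 identifiers that rose and 2 that fell per comparison, those with the largest difference among probes past the threshold with the same sign in all 3 DMBQ replicates, from the fit with the block where fewer than 10 passed. Lists of genes fixed beforehand for hormones, cell wall, redox, stress and cell types could not be applied, since the files do not pair contigs with gene names and no reference was given; their set tests were not run.

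The labels number the DMBQ replicates and, per the file headers, each number is 1 slide with 1 scan time. The labels' descriptions give 2 slide numbers and the file headers 4 slides; the block and every comparison between slides rest on the headers. Deviations of same-numbered arrays from their time means correlated at a median r of 0.456, with 83 of 84 pairs over 0.1 and the lowest at 0.0943, and all 24 arrays correlated best with their own number. The number was therefore taken as a shared slide, and the fit with it as a block is printed beside the fit without it. On every slide the 0 and 6 h arrays shared a column, as did 0.5 and 12 h, 1 and 24 h, and 3 and 48 h. The labels call the DMBQ replicates biological replicates and say no more about what was shared between them.

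The fits were tested on simulated data for 30968 probes with the real probe means, slide effects and residual spread per probe. Noise was normal, independent between probes and equally wide on all arrays, whereas residual SDs of the DMBQ arrays ran from 0.26 to 0.52. The simulations thus hold no deviation shared by the probes of an array. Their recovered shares and false calls hold only for such noise. For DMBQ 1 h against 0 h, the fit without the block recovered 44.8%, 71.6% and 80.3% of probes changed by 1.5, 2 and 3 log2 units, with 2 false calls, and the fit with it 65.7%, 91% and 97%, with 5. For DMBQ against mock at 1 h these shares were 4.48%, 10.4% and 27.3% without the block, with 0 false calls, and 29.9%, 37.3% and 62.1% with it, with 7. Sequences placed 10 or 15 times on an array differed between spots by a median SD of 0.07 to 0.15 log2 units. Alternatives covered background correction, scaling, quantile normalization, filters, outlier spots, the block, leaving out each replicate, leaving out 3 arrays, and thresholds.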

Results

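The root transcriptome of *Phtheirospermum japonicum*, a facultative root parasite of the broomrape family, was measured after treatment with 2,6-dimethoxy-p-benzoquinone (DMBQ). DMBQ is a quinone that induces the haustorium, the organ with which parasitic plants attach to and draw on a host root. Roots of 2-week-old seedlings received 10 µM DMBQ and were sampled at 0 h, at 0.5 and 1 h, and at 5 later times, 3, 6, 12, 24 and 48 h, with 3 biological replicates per time. Mock roots received the solvent, DMSO, and were sampled once per time. The 32 one-colour arrays comprised 24 DMBQ arrays and 8 mock arrays. They lay on 4 slides, so that each DMBQ replicate number was 1 slide and the mock series was another. The treatments were therefore compared after each series was set against its own 0 h array. This removes only a slide effect that is constant over time. A slide difference that changes with time cannot be told apart from treatment. The 75th percentile of signal ran from 151 to 204 intensity units on the replicate 2 slide, the dimmest, and from 294 to 794 on the replicate 1 slide. Between 50.9% and 65.6% of the 48023 probes shared by both array designs were well above background on an array. The number of arrays, 3 per DMBQ time and 1 per mock time, limits the precision of each value. The deposited files name each probe only by the assembly contig it was designed on, so contigs are given by their identifiers and no gene function is assigned.

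The first comparison asked which transcripts changed in DMBQ roots relative to DMBQ roots at 0 h. Calls were most numerous at 0.5 and 1 h and mostly upward. At 0.5 h 431 probes rose and 50 fell, and at 1 h 440 rose and 72 fell, out of 30968 tested. Single slides, counted without a test, ran the other way at 0.5 h. On replicates 1, 2 and 3, 3627, 1636 and 1779 probes lay at least 2-fold below 0 h. Those at least 2-fold above numbered 1941, 1481 and 1236. At 1 h falls outnumbered rises on replicate 3 alone (1846 and 1493). The contig with the largest rise at 0.5 h under the naming rule, Pj3contig_43809, was not well above background on any of the 3 arrays at 0 h and was at least 115-fold higher at 0.5 h (limma adjusted p = 1.6e-06, n = 3 per time) and at least 56.9-fold higher at 1 h. Pj3contig_42345, well above background on 1 of the 3 arrays at 0 h, rose by 7.55 ± 0.74 on the log2 scale (SE, n = 3 per time, adjusted p = 7.2e-06) at 0.5 h and by 8.09 ± 0.74 at 1 h, and at 6 h it stood 0.38 ± 0.74 above its 0 h level. Pj3contig_13750 fell by 3.46 ± 0.55 at 1 h (adjusted p = 0.0011) and at 3 h lay 0.37 ± 0.55 log2 units below 0 h, a difference within its error. In the fit without the block its call at 1 h ended without replicate 2 (adjusted p = 0.27). With the slide as a block and all replicates, limma's adjusted p at 1 h was 0.00075. Pj3contig_22717 fell by 3.23 ± 0.67 at 0.5 h (adjusted p = 0.012, and 0.012 with the block). In the fit without the block that call ended without any 1 of the 3 replicates. It also ended under normexp background correction (-0.95, adjusted p = 0.55). That correction, whose offset of 50 compresses the changes of dim probes, also gave Pj3contig_43809 a rise of 4.47 at 0.5 h in place of the fitted 7.69, that is 22.1-fold and below the bound of 115-fold, and 11.3-fold at 1 h. It gave Pj3contig_42345 rises of 4.47 at 0.5 h and 5.04 at 1 h, and Pj3contig_13750 a change of -1.98 at 1 h. The sets of risen probes at 0.5 and 1 h had 280 members in common. Independent lists of these sizes would share 6.12. Lists of the same lengths, taken by smallest p among rises, shared 271 probes in the data and a mean of 90.6 in 20 simulations with no effect and the same shared 0 h arrays. The simulations hold no deviation shared by the probes of an array, which could raise the overlap. Part of the excess may therefore come from the 3 shared 0 h arrays, which are too few to split. The test was a limma fit over the 24 DMBQ arrays with Benjamini-Hochberg adjustment. With the slide as a block the calls rose to 618 higher and 146 lower at 0.5 h and to 710 higher and 197 lower at 1 h. With each array's percentile taken over all probes of its own design, which adds an offset between designs to the spread, the totals were 116 at 0.5 h and 90 at 1 h in the fit without the block and 779 and 879 with it. Without 1 DMBQ slide the totals in the fit without the block were 150 to 234 at 0.5 h and 67 to 323 at 1 h, lowest without replicate 2 at both times.

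**Figure D1:**
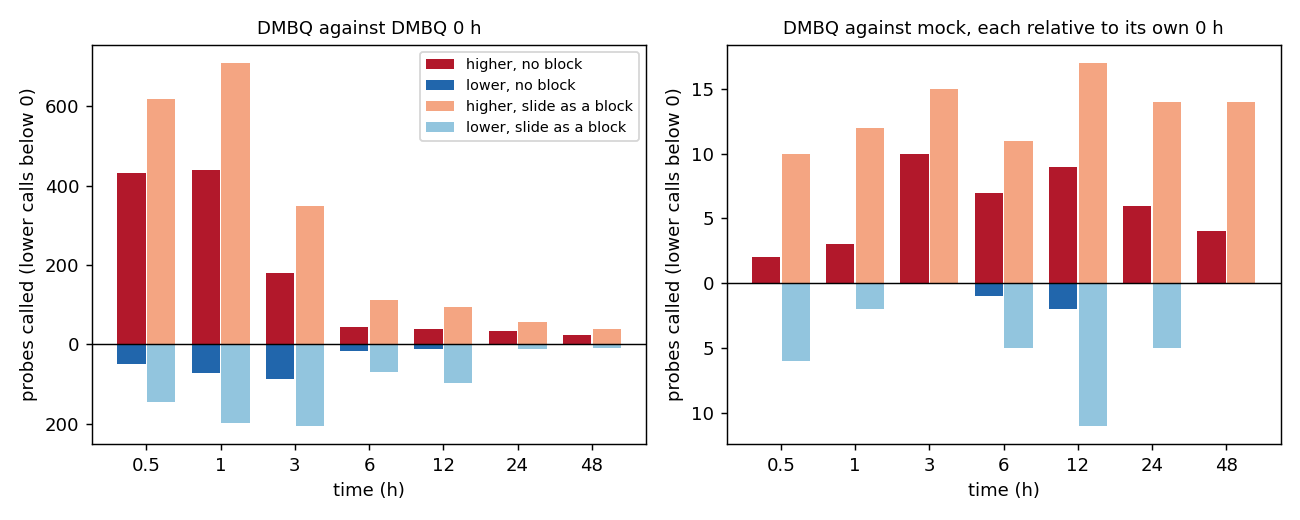
Probes called higher (above 0) and lower (below 0) at each time, in DMBQ roots against DMBQ 0 h (left) and in DMBQ against mock roots, each relative to its own 0 h (right, on a smaller axis). Dark bars are the fit without a block and light bars the fit with the slide as a block; on the left the dark bars reach 440 higher at 1 h and drop to 24 at 48 h.

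From 3 h on fewer probes passed the threshold against 0 h, and a small set stayed high. At an unadjusted p under 0.05 in the limma fit without the block the drop came later. In either direction, 3066, 2398, 2539, 1359 and 1534 probes had such a p at 0.5, 1, 3, 6 and 12 h. A uniform p with no effect would give a share of 0.05 of the 30968 tested probes. The counts at 6 and 12 h did not exceed that share. With the slide as a block they were 3722 and 3955 and exceeded it. At 3 h 181 probes rose and 88 fell. At 6 h 45 rose and 17 fell, and at 12 h 40 rose and 12 fell. Of the named contigs Pj3contig_22303 had the largest fitted rise at 3 h, 6.57 ± 0.29 (SE, n = 3 per time, adjusted p = 5.6e-11), with 6.19, 6.12 and 7.40 in the 3 replicates, and it was still 4.11 ± 0.29 higher at 48 h. Pj3contig_30986 was not well above background at 0 h and was at least 17.4-fold higher at 3 h (adjusted p = 4.9e-08) and at least 23.9-fold higher at 6 h; under normexp it was 4.56-fold and 6.77-fold higher, below these bounds, and still passed (adjusted p = 0.0051 and 0.0011). Among contigs that fell, Pj3contig_21677 dropped by 4.45 ± 0.85 at 3 h (adjusted p = 0.011; -2.76 under normexp), and Pj3contig_45445 fell by 3.16 ± 0.35 at 3 h and fell by 2.55 ± 0.35 at 6 h (adjusted p = 0.001 at 6 h). Pj3contig_56225 fell by 3.27 ± 0.53 at 6 h (adjusted p = 0.0073). In the fit without the block, the call for Pj3contig_21677 at 3 h ended without any 1 of the 3 replicates. There the call for Pj3contig_45445 at 6 h ended without replicate 1 or 3. That for Pj3contig_56225 at 6 h ended without replicate 2 or 3. Leaving out a replicate was not run with the block against 0 h. With the block and all replicates, limma's adjusted p for these calls were 0.003, 0.00094 and 1.9e-05. With the slide as a block, 350 rose and 206 fell at 3 h, 111 and 70 at 6 h, and 94 and 97 at 12 h. Scaling to the array median moved the split at 6 h from 45 higher and 17 lower to 46 and 8, and at 12 h from 40 and 12 to 37 and 3; without the 3 arrays that lay farthest from the fit, 34 probes passed the threshold at 12 h instead of 52.

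At 24 and 48 h the calls were rises. At 24 h 33 probes rose and at 48 h 24 rose, and limma called 0 lower at both times. In either direction, 571 and 433 probes had an unadjusted p under 0.05 in the limma fit without the block. With the slide as a block 1462 and 1236 had such a p. All 4 counts lie below a share of 0.05 of the 30968 tested probes, so they give no excess over that share. The 24 probes that rose at 48 h were all among the 33 of 24 h, where independent lists would share 0.0256 and lists of these lengths from the simulations with no effect shared a mean of 2.45 and at most 5. As the simulations hold no deviation shared by the probes of an array, part of the excess may come from the shared 0 h arrays. Pj3contig_2976 was not well above background at 0 h on any array. It was at least 46.4-fold higher at 12 h, at least 170-fold higher at 24 h (adjusted p = 2.5e-07) and at least 81.6-fold higher at 48 h. Under normexp it was 11.6-fold, 39.0-fold and 18.9-fold higher at these times, below the bounds, and still passed (adjusted p = 0.0094, 6.3e-05 and 0.0021). Pj3contig_20736, well above background on 1 of the 3 arrays at 0 h, rose by 6.34 ± 0.38 at 6 h, 7.77 ± 0.38 at 12 h and 8.25 ± 0.38 at 24 h (adjusted p = 3e-10), and stood 7.52 ± 0.38 above 0 h at 48 h. Because 2 of its 3 arrays at 0 h were not well above background, these sizes rest on dim signals; under normexp they were 3.46, 4.86, 5.28 and 4.54, and all passed. A second probe for this contig on the second array design was not well above background on any of its 16 arrays. With the slide as a block, 56 probes rose and 11 fell at 24 h, and 39 rose and 8 fell at 48 h. Over all 7 times, limma's F-test called 856 probes without the block and 2372 with it.

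The mock series asked how much of this course also took place without DMBQ. At 0.5 and 1 h most of the probes that rose in DMBQ roots were also higher in mock roots. Of the 431 probes that rose at 0.5 h, 97.4% also moved upward in mock roots, and 339 of them were at least 2-fold above the mock 0 h array; at 1 h 96.8% of 440 moved upward in mock roots. The median change of the 0.5 h set was 1.95 log2 units in DMBQ and 1.64 in mock roots, and by 6 h it was 0.13 and -0.15. Pj3contig_42345 stood 6.10 above the mock 0 h array at 0.5 h, and Pj3contig_13750 stood at -3.30 at 1 h. Because probes chosen on the DMBQ arrays look larger there, the comparison was repeated with probes called from 2 DMBQ replicates and measured in the third, held-out slide. For risen probes, the mock median at 0.5 h was 82.2% to 92.8% of the held-out DMBQ median, and at 1 h 66% to 103%. At 3 h it was 23.2% to 35.9%, at 6 h 8.68% to 13.9%, at 24 h 6.45% to 11% and at 48 h 3.25% to 8.68%. At 6, 24 and 48 h these sets held 8 to 20 probes. At 12 h it was 7.55% and 11.8% with replicates 3 and 2 held out (20 and 16 probes, mock medians 0.341 and 0.512). With replicate 1 held out it was 145% (34 probes). There the replicate 1 array rose by a median of only 0.904, but the mock median was also higher, 1.31, so the mock share at 12 h is not settled. Fewer probes fell. With replicates 1, 2 and 3 held out in turn, the mock median was 193%, 153% and 22.5% of the held-out one at 0.5 h (12, 5 and 7 probes), 127%, 78.2% and 118% at 1 h (38, 2 and 31 probes) and 54.6%, 60.6% and 56.8% at 3 h (13, 22 and 40 probes). At 6 h it was 17.6% for 1 probe and 103% for 6 with replicates 1 and 2 held out. At 12 h it was -118%, 36.3% and -16.8% (5, 1 and 6 probes), so that in 2 of the 3 hold-outs the medians had opposite signs. At 24 and 48 h 2 probes or fewer fell in any hold-out. Across probes, the changes at 0.5 h on the 3 DMBQ slides correlated with each other at r = 0.29 to 0.49 and with the mock slide at 0.19 to 0.43; at 1 h these ranges were 0.19 to 0.51 and 0.44 to 0.52. Probes are not independent replicates, and with 1 mock array per time no test of the mock course itself was made.

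**Figure D2:**
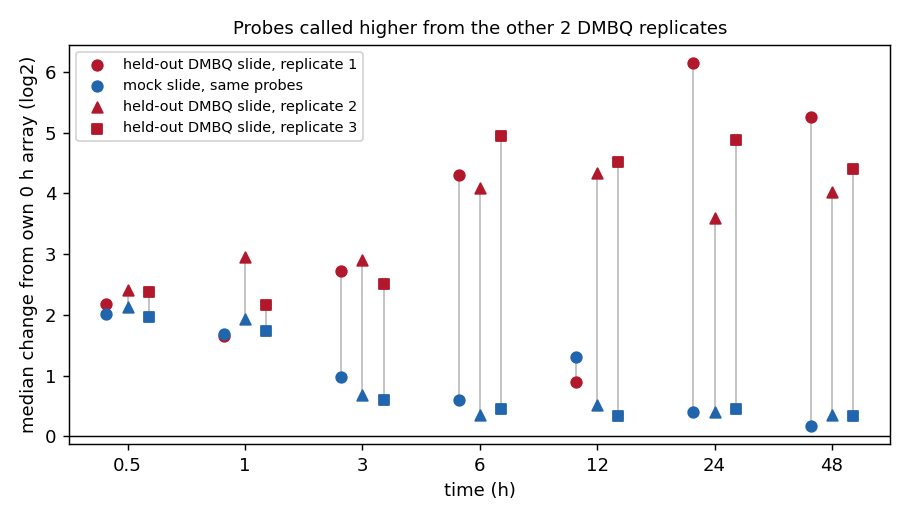
Median log2 change from the slide's own 0 h array of probes called higher from 2 DMBQ replicates, in the held-out DMBQ replicate (red) and in the mock series (blue, same marker shape for the same probes), by time in h. The 2 medians lie close at 0.5 and 1 h, except with replicate 2 held out at 1 h (2.95 and 1.94). They lie apart from 3 h on, as at 24 h, where the held-out medians are 3.60 to 6.15 and the mock medians 0.396 to 0.449. At 12 h the replicate 1 pair is the exception.

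The comparison of DMBQ with mock roots tested whether the change from 0 h differed between the treatments. Few probes passed, and most of the calls were higher with DMBQ. The totals were 2 probes at 0.5 h, 3 at 1 h, 10 at 3 h, 8 at 6 h, 11 at 12 h, 6 at 24 h and 4 at 48 h; 1 of the calls at 6 h and 2 at 12 h were lower. This direction depended on the setting: without the filter on dim probes 7 were higher and 14 lower at 6 h and 9 and 30 at 12 h, and in the direct difference without the 0 h baseline 13 and 16 at 6 h, 16 and 24 at 12 h, and 5 and 6 at 0.5 h. Of the 431 probes that rose at 0.5 h against 0 h, 2 also passed this test. Pj3contig_46280 passed at all 7 times. It was well above background on all 21 treated DMBQ arrays and on none of the 3 DMBQ arrays at 0 h, and on 1 of 8 mock arrays, that of 0 h. At 3 h it was at least 15.1-fold over DMBQ 0 h (4.01-fold under normexp) and at least 27.6-fold over mock roots at 3 h (adjusted p = 3e-07 for the difference in change). Its change in mock roots at 3 h was -1.37, which adds to the tested difference of 7.03. Pj3contig_22303 was measured on all 32 arrays, and its rise at 3 h exceeded that in mock roots by 6.38 ± 0.57 (SE; adjusted p = 1.6e-05), while mock roots stood 0.19 above their own 0 h level. Pj3contig_30986 was not well above background on any mock array and was at least 38.5-fold over mock at 6 h (adjusted p = 5.8e-05). Pj3contig_4721 was at least 18.6-fold over mock at 12 h (adjusted p = 0.024) and at least 106-fold at 24 h (adjusted p = 0.00068). Of the mock arrays only that of 0 h was well above background for it, and its mock change of -2.81 at 12 h adds to the tested 7.14. Pj3contig_2976 was at least 215-fold over mock at 24 h (adjusted p = 0.023). These bounds against mock set arrays on different slides against each other. Each adjusted p beside them belongs to the difference in change from 0 h between the treatments, not to the bound. Under normexp these calls for Pj3contig_46280, Pj3contig_30986, Pj3contig_4721 and Pj3contig_2976 ended, with an adjusted p of 0.28 for Pj3contig_4721 at 24 h and of 1 for the others, while Pj3contig_22303 still passed at 3 h (5.82, adjusted p = 5.4e-05). With the percentile over all probes of a design and no block, the calls for Pj3contig_46280 at 3 h, Pj3contig_30986 at 6 h, Pj3contig_4721 at 12 h and Pj3contig_2976 at 24 h also ended. With that percentile and the block, 15, 16, 28 and 17 probes were called at 3, 6, 12 and 24 h. In the fit without the block, the calls for Pj3contig_2976 at 24 h and for Pj3contig_4721 at 12 h ended without any 1 of the replicates. With the block and all replicates, limma's adjusted p was 0.017 for each. Pj3contig_20736 stood 4.30 above the mock 0 h array on the mock array of 24 h. Pj3contig_48881 exceeded mock by 4.64 ± 0.89 at 0.5 h, with adjusted p = 0.18 without the block and 0.00013 with it. Pj3contig_51903 passed at 3 h (adjusted p = 0.036) but read 3.98 on the mock 0 h array and -4.30 on the mock 3 h array, and the direct difference of DMBQ over mock roots was 0.33 at 0.5 h, 0.05 at 3 h, and -0.57, -1.13, -0.96, -0.20 and -0.15 at 1, 6, 12, 24 and 48 h.

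The test for DMBQ against mock treated the lone mock array of each time as varying like the DMBQ replicates. With the slide as a block the totals were 16, 14, 15, 16, 28, 19 and 14 from 0.5 to 48 h, and 58 probes passed at any time, 31 higher and 27 lower, against 18 without the block. When each DMBQ slide was set in place of the mock slide against the other 3, it gave 0 to 819 calls at a single time, so the number of calls does not by itself mark the mock slide as different. At 1 h, the simulation of this comparison without the block recovered 27.3% of probes changed by 3 log2 units, so a probe that did not pass was not shown to be alike in both treatments.

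**Figure D3:**
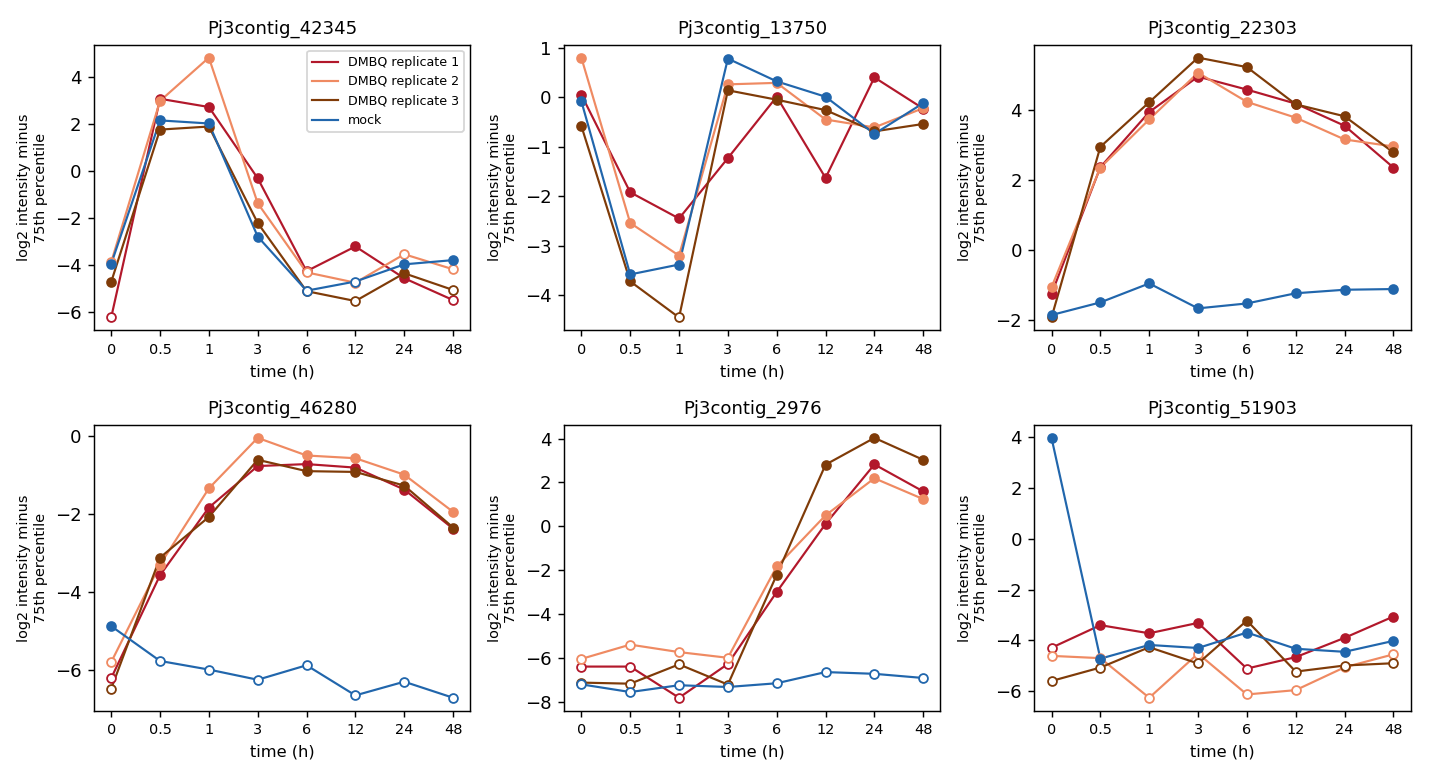
Normalized log2 intensity (log2 minus the array's 75th percentile) of 6 contigs by time in h on each of the 32 arrays, 1 line per DMBQ replicate and 1 for mock; filled points are well above background and open points are not. Pj3contig_42345 and Pj3contig_13750 moved in all 4 series, Pj3contig_22303, Pj3contig_46280 and Pj3contig_2976 in the 3 DMBQ series, and Pj3contig_51903 stands at 3.98 on the mock 0 h array alone.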

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

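The turns of each slide as the lone arm over several times were chosen after the results were seen; the other tests in this part were planned before.

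The change from 0 h differed between DMBQ and mock roots, by the test of that difference, for 2 probes at 0.5 h, 3 at 1 h, 10 at 3 h, 8 at 6 h, 11 at 12 h, 6 at 24 h and 4 at 48 h. With the slide as a block, 31 probes were higher with DMBQ at some time. A fault of single probes was tested on the 10 of these contigs that have a second probe on the replicate 3 and mock slides. The second probes' median difference was 86.7% of the first probes', which argues against it for the set, although for 3 of the 10 the second probe showed under 50% of the difference, Pj3contig_20736 among them, whose second probe was not well above background. An error of the mock 0 h array was tested by comparing DMBQ and mock directly at the same time. The direct difference had a median 78.6% of the baseline-corrected one, which argues against this for the set. For 4 contigs, among them Pj3contig_51903, it was under 25%. Pj3contig_51903 changed by -7.67 to -8.70 from the mock 0 h array over the 7 mock times, and its median direct difference was -0.20. Its calls as higher with DMBQ therefore rest on the mock 0 h array, and whether that reading was an error was not tested. For the others the mock 0 h array stays open as the source.

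Chance is not settled for this comparison. Setting each of the 4 slides in turn against the other 3 gives 4 arrangements, too few for a share under 0.05. Of these, 4 gave at least as many calls as the mock slide at 0.5 h, 4 at 1 h, 3 at 3 h, 4 at 6 h, 3 at 12 h, 2 at 24 h and 2 at 48 h. The highest counts with a DMBQ slide in place of mock were 343, 9, 583, 61, 819, 11 and 4. Counts of 343, 583 and 819 came from replicate 1 at 0.5 h, replicate 3 at 3 h and replicate 1 at 12 h, so they point to single arrays. Probes lower on the lone slide at 3 or more times numbered 7 for mock, 10 for replicate 2, 2 for replicate 1 and 2 for replicate 3. The calls are therefore not called biological, and DMBQ itself stays an open explanation.

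For the DMBQ times against 0 h, 3 arrays against 3 make 10 splits, too few for a share under 0.05. The real split, 1 of the 10, called 481, 512, 269, 62, 52, 33 and 24 probes from 0.5 to 48 h, and the highest other split called 1, 2, 0, 0, 0, 0 and 0. The 4 splits that keep 1 array of each slide on either side, the real one included, gave 0 calls apart from the real one. For the F-test, 1 of 100 regroupings of the 24 arrays, the real one, called as many probes. The regroupings moved arrays freely between slides in the fit without a block. They ignore the spread that arrays of a slide share, so they do not settle chance. The real count was 856 and the highest other 679, with a median of 0, and 3 other regroupings exceeded 100.

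A signal was also present in probes outside the comparisons. The first array design carries 10361 probes under another naming scheme that the second lacks, and 1302 of them were well above background on all 16 arrays of replicates 1 and 2. Between 32.3% and 55.8% of them exceeded the 95th percentile of the negative control spots.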

How the results depend on the processing

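The normexp correction on median signals, the percentile over all probes of a design (without and with the block), the fit without 3 arrays, the mean of the 7 times and the block with each replicate left out were chosen after seeing the data; the other alternatives were planned. In every alternative listed here that gave calls against 0 h at 0.5 and 1 h, more of the called probes rose than fell. Untested counts at 2-fold on each of the 3 DMBQ slides ran the other way at 0.5 h. Signal limits the dim probes: 30968 of 48023 shared probes passed the filter. Scaling to the array median moved the median of all tested probes by up to 0.21 log2 units, from -0.02 to 0.19 at 0.5 h. The cause was not tested except where the setting's construction shows it.

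With the replicate block, which removes the spread between slides, the counts against 0 h were 764, 907, 556, 181, 191, 67 and 47 from 0.5 to 48 h and 2372 in the F-test, and the counts against mock were 16, 14, 16, 28, 19 and 14 at 0.5, 1, 6, 12, 24 and 48 h. All calls without the block, both against 0 h and against mock, were also called with it. With the slide as a random block (consensus correlation 0.422) the counts against 0 h were 798, 937, 569, 177, 169, 64 and 47 from 0.5 to 48 h and 2351 in the F-test, and the counts against mock were 16, 13, 19, 22, 18 and 13 at 0.5, 1, 6, 12, 24 and 48 h.

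With the percentile over all probes of each design, which adds the offset between designs to the spread of the fit without a block, the counts against 0 h were 116, 90, 76, 27 and 24 at 0.5, 1, 3, 6 and 12 h and 214 in the F-test, and the counts against mock were 1, 1, 3, 0, 0, 1 and 0 from 0.5 to 48 h and 5 for the mean of the 7 times. With the same percentile and the replicate block the counts against 0 h were 779, 879, 533, 187, 189, 67 and 46 from 0.5 to 48 h and 2282 in the F-test, and the counts against mock were 16, 13, 16, 28, 17 and 14 at 0.5, 1, 6, 12, 24 and 48 h. With normexp on median signals the counts against 0 h were 285, 286, 124, 24, 21, 19 and 7 from 0.5 to 48 h and 519 in the F-test, and the counts against mock were 1, 2, 2, 3, 3 and 2 at 0.5, 3, 6, 12, 24 and 48 h and 3 for the mean of the 7 times. Pj3contig_51903, which read 3.98 on the mock 0 h array alone, was among these calls at each of these times (limma adjusted p = 0.0014 to 0.0053). It was the only call at 0.5 h. With quantile normalization the counts against mock were 4, 6, 12 and 8 at 0.5, 1, 24 and 48 h. With scaling to the array median the counts against mock were 1 at 1 h. With no filter on dim probes, which adds probes to the test, the counts against mock were 5, 21 and 39 at 3, 6 and 12 h. With only probes above background on every array, which leaves fewer probes tested and removes those that were silent in a group, the counts against 0 h were 36, 24, 13 and 10 at 6, 12, 24 and 48 h, and the counts against mock were 4, 2, 1, 1 and 0 at 3, 6, 12, 24 and 48 h and 5 for the mean of the 7 times. With outlier spots kept the counts against mock were 5 at 0.5 h. Without the 3 arrays farthest from the fit the counts against 0 h were 34 at 12 h, and the counts against mock were 6 and 5 at 1 and 12 h. At adjusted p under 0.01 the F-test called 534 probes. In the direct difference without the 0 h baseline, where treatment and slide are not separated, the counts against mock were 11, 15, 16, 29, 40, 25 and 20 from 0.5 to 48 h. Without the block, dropping the fold minimum moved no count by over 1.5 times; with the block it moved the count at 3 h against 0 h from 556 to 903.

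The split between higher and lower calls against 0 h moved by over 10 percentage points at 3, 6 and 12 h in some scalings. At 3 h it was 181 higher and 88 lower, and 42 and 34 with the percentile over all probes of a design. At 6 h it was 45 and 17, and 46 and 8 with the array median, 14 and 10 with normexp and 24 and 3 with that percentile. At 12 h it was 40 and 12, and 37 and 3, 19 and 2, and 23 and 1. Against mock, calls at 0.5 h were 2 higher and 0 lower, and 1 and 1 with the array median and 3 and 1 with quantile normalization; at 1 and 24 h quantile normalization gave 5 and 1, and 9 and 3, against 3 and 0, and 6 and 0; normexp gave 2 and 1 at 24 h; at 6 and 12 h normexp gave no lower call, with 2 and 3 higher. Without the filter on dim probes the calls against mock were 7 higher and 14 lower at 6 h and 9 and 30 at 12 h, instead of 7 and 1, and 9 and 2. In the direct difference they were 5 and 6 at 0.5 h, 11 and 4 at 1 h, 16 and 0 at 3 h, 13 and 16 at 6 h, 16 and 24 at 12 h, 13 and 12 at 24 h and 15 and 5 at 48 h.

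With 1 replicate left out, which leaves fewer arrays, the counts against 0 h were 150 to 234 at 0.5 h, 67 to 323 at 1 h, 54 to 105 at 3 h, 16 to 23 at 6 h, 17 to 39 at 12 h, 12 to 22 at 24 h, 8 to 16 at 48 h and 125 to 461 in the F-test, and those against mock 0 to 3 at 0.5 h, 0 to 4 at 1 h, 2 to 7 at 3 h, 3 to 6 at 6 h, 2 to 7 at 12 h, 1 to 6 at 24 h, 1 to 3 at 48 h and 3 to 5 for the mean of the 7 times. With the replicate block as well, those against mock were 2 to 6 at 0.5 h, 6 to 11 at 1 h, 7 to 11 at 3 h, 5 to 10 at 6 h, 5 to 18 at 12 h, 3 to 12 at 24 h, 2 to 4 at 48 h and 6 to 10 for the mean of the 7 times.

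For named contigs, 534 values kept their direction and side of the threshold, 85 came to pass it, 103 no longer passed and 3 reversed. The reversals were Pj3contig_51903 against mock without the 0 h baseline, at -0.57 at 1 h, -1.13 at 6 h and -0.15 at 48 h (limma adjusted p = 1 each); by construction the baseline is the mock 0 h array, which read 3.98. Under normexp, whose offset of 50 shrinks changes of dim probes by construction, all 24 named values against 0 h were smaller, 21 of them by over 1.5 times, and 6 no longer passed; Pj3contig_43809 at 0.5 h was 4.47 instead of 7.69 and Pj3contig_42345 4.47 instead of 7.55. Against mock all 24 were smaller, 16 by over 1.5 times, 9 no longer passed and 5 came to pass. Those 5 each rest on a single mock array. They were Pj3contig_51903 at 0.5, 1, 6 and 48 h and Pj3contig_1693 at 24 h. The latter read 2.86 on the mock 24 h array and at most -4.26 on the other mock arrays. Not run were the authors' normalized table, whose columns match no label, normexp on mean spot signals, which the files used here do not hold, and the set tests with their alternatives, for want of gene names.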

Other observations

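The place-on-slide tests and the signal test in this part were chosen after the result was seen; the others were planned before.

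The 88 probes that fell at 3 h in DMBQ roots had a median of -2.28 log2 units at 3 h, -1.48 at 6 h and -1.44 at 12 h in DMBQ roots, and -1.08, -0.76 and -0.11 in mock roots. They were chosen on the DMBQ arrays, which enlarges the DMBQ values. Their difference between the treatments was not tested as a group, and limma called 0 of the 88 lower against mock at 3 h, without and with the block. The 33 probes that rose at 24 h had DMBQ medians of 0.25 at 0.5 h, 2.52 at 3 h and 3.85 at 24 h, and mock medians between -0.35 and 0.46 over the 7 times.

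Most probes that rose in DMBQ roots at 0.5 and 1 h were also higher than at 0 h in mock roots. A response to handling that both treatments share, such as the change of position and the cover, may account for this. The lowest of 6 percentages of mock over held-out DMBQ medians was 66, above the 50 that this explanation requires. Any cause that both treatments share would give such a value, so this does not favour handling over the others. The percentages also rest on 1 mock array per time. Place on the slide was also weighed, because the 0, 0.5 and 1 h arrays lie in the same columns as the 6, 12 and 24 h arrays: for the 431 probes that rose at 0.5 h, the 12 h minus 6 h difference on the replicate 2, replicate 3 and mock slides was at most 1.55% of the 0.5 h minus 0 h difference, which argues against it for the 0.5 h rise on these slides. On the replicate 1 slide it was 14.3%, but there the 2 differences correlated across all probes at r = 0.55, against -0.11, -0.09 and 0.04 on the other slides, so place stays open for the 0.5 h rise on that slide. For the 440 probes that rose at 1 h, the 24 h minus 6 h difference was compared with the 1 h minus 0 h difference. On the replicate 1, 2, 3 and mock slides it was -17.3%, -0.315%, 1.45% and 19.9% of it. Across all probes these differences correlated at -0.09, 0.19, -0.01 and 0.11. This argues against place for the 1 h rise on the replicate 1 and 3 slides. On the replicate 2 and mock slides the correlations leave place open. The solvent and other conditions common to both treatments stay open as untested.

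Arrays of DMBQ at 3 h replicate 3, 12 h replicate 1 and 0.5 h replicate 1 lay farthest from the fit of time and slide, with residual SDs of 0.52, 0.47 and 0.38 log2 units against 0.26 to 0.36 for the other 21. The 3 arrays' deviations correlated across probes at 0.13 to 0.20, between the bounds set for and against 1 shared source such as RNA quality, so this cannot be told apart from separate causes. The 3 h replicate 3 array had 226 flagged spots, against at most 90 on any other array, and the highest SD between repeated spots, 0.15. The 0.5 h and 12 h replicate 1 arrays had 21 and 13 flagged spots and SDs of 0.092 and 0.088. Low signal in comparison with all DMBQ arrays is argued against: the 3 arrays' 75th percentiles were 341 to 519, and 10 of the other 21 arrays were dimmer than 341, with residual SDs of at most 0.36. The 8 arrays of the replicate 2 slide, at 151 to 204, are among these 10, so this compares mostly between slides. On the replicate 1 slide, which holds 2 of the 3 arrays, low signal within the slide stays open. Over the 24 arrays Spearman's rho of the 75th percentile with the residual SD was -0.15 (permutation p = 0.48, two-sided) and Pearson's r -0.11 (permutation p = 0.62), or 0.17 without the 2 arrays farthest from the median signal. Within the slides of replicates 1, 2 and 3 rho was -0.61, 0.02 and 0.06. No biological explanation was tested.

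The probes called lower in DMBQ against mock with the slide as a block were set against the single mock arrays. There were 29 such calls in 27 contigs. In 26 of the 29 the mock array of that time was the highest of the 8 mock arrays, and in 28 it lay above all 24 DMBQ arrays. With 1 mock array per time, a lower call needs that array to be high. These counts therefore largely follow from how the probes were chosen and do not show the source of the calls. For 11 of the 27 contigs no DMBQ array was well above background.

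Probes outside the shared set were tested apart. Of the 10361 on the first design, 2314 were tested with 2 replicates per time, and 3 rose at 1 h and 1 at 3 h without the block. In the fit with the block, 6 rose and 1 fell at 1 h, 4 and 4 at 3 h, 4 and 3 at 6 h, and 1 rose at 12 h and 1 at 24 h. On the second design, 10490 further probes are second probes of contigs already measured; across 9255 of them, levels on the replicate 3 array at 0 h correlated with the first probe at r = 0.969 and changes at 1 h at 0.906.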
